A study of Mus musculus with 24 samples.

How the data were processed

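RNA from C57BL/6J mouse liver was measured on 24 single-colour arrays (Agilent SurePrint G3 Mouse GE v2 8x60K, Cy3 dye). Per the labels, the arrays fall into 4 groups of 6 liver samples, male or female mice on a control diet or on the same diet with a mixture of pesticides for 52 weeks. The labels give 6 liver samples per group and no mouse number, so the p-values measure the spread between samples, which are separate mice only as far as those labels say. Each of the 3 slides carried 8 arrays, 2 of each group, and all were scanned on 1 day.

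Per the file headers, the deposited scanner files hold spot signals as fluorescence intensity with their local background and quality marks, extracted by Agilent Feature Extraction 10.10.1.1 according to the submitters' processing notes. The deposited value table holds log2 values, which per the labels the authors made from the median signal by filtering, log2 transformation and quantile normalization; the notes do not give the filter. The submitters' processing notes also name limma for their comparisons, with Benjamini-Hochberg adjustment. Each of the 24 scanner files was checked against the value table and correlated best with its own column.

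The median spot signal was used on the log2 scale, with no background subtraction. Of 62976 spots per array, 3671 control spots were left out, since they carry no mouse gene. The remaining 59305 spots made 56605 probes, of which 300 were printed 10 times. Spots marked as non-uniform outliers were set to missing (0 to 9 per array), spots of a probe were averaged, and all arrays were quantile normalized over the 56605 probes. A probe was tested when the scanner's mark "well above background" was set on at least 4 of the 6 arrays of at least 1 group, which left 32078 probes. Gene names came from the RefSeq accession given for the probe, or else from the file's own gene name; 26573 tested probes had a name, for 15949 genes. Probe positions are on the mouse build mm9, per the file headers.

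Arrays give no counts, and the number of arrays limits the precision. Between 29935 and 39032 probes per array were well above background (median 31519), the median spot signal was 58 to 101.5, and 0 spots were saturated. Where a gene was well above background on no array of its dim group, the fold is a bound. It was computed from the bright group's mean over all replicates against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

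One mean per group was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes), with no block. The groups share the estimate of the spread. Leaving out an array outside a comparison therefore leaves the differences unchanged and acts through that shared spread. All tests were two-sided, and probes passed at a Benjamini-Hochberg adjusted p under 0.05 over the tested probes. The contrasts were labelled pesticide against control within each labelled sex, their mean, their difference (interaction), and labelled male against female within each labelled diet. Log2 fold changes are given with the standard error (SE) from limma, and group means with the standard deviation (SD) over 6 arrays. Across genes, the male and female effects were correlated and compared with 100 regroupings of the diet labels within each labelled sex, the real one included.

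A gene was represented by its brightest tested probe. The genes named are the 12 highest and 12 lowest passing log2 fold changes for the pesticide comparisons, up to 4 members with the smallest p of each gene list, and 15 genes chosen in advance. For the interaction, which called no gene, they are the 4 with the smallest p in each direction. Genes with only a clone or predicted name were counted and not described, and 1 gene that the rule names is not reported here. Gene lists, 36 in all (23 of pathways, 13 of cell markers, 770 genes, 50 of them in more than 1 list), were tested with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation, and fry, which asks whether a list's genes move on balance one way, were run beside it, each adjusted over the 36 lists. The comparisons, the lists, the naming rule and the alternatives were fixed before the data were examined.

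Alternatives were normexp background correction with an offset of 50, scaling of the median or of the processed signal to the 75th percentile, no filter on dim probes, only probes well above background on all arrays, outlier spots kept, a slide block, each slide alone, a replicate block, only the arrays compared, eBayes with trend and robust settings, array weights, the deposited value table, 1 probe per gene, and leaving out each array. The correlation was also computed without clock genes and without sex-biased genes. Chosen after the data were seen were counts without X and Y probes, list counts without labelled female control 4 and without labelled female pesticide 3, a labelled sex contrast averaged over the diets, permutation tests of list means, their repeat over both labels without labelled female control 4, and the AhR target genes without each member. In simulated data of the same size, probes shifted by 1 log2 unit were called in 88.1% to 98.5% of cases across the 6 contrasts. Those shifted by 0.5 were called in 22.4% of cases in the interaction, 59.7% for labelled sex under the control label and 68.7% to 82.1% in the other contrasts. A gene list shifted by 0.3 was recovered by camera at the preset correlation with no other list called. The simulated genes varied independently of each other. Genes of a real list can vary together, so this does not show how often camera calls lists falsely here.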

Results

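Gene expression was measured in the livers of C57BL/6J mice whose labels put them in 4 groups of 6 arrays: male control, male pesticide, female control and female pesticide. The pesticide groups were labelled as fed a diet with a pesticide mixture for 52 weeks. Of the 32078 probes tested, 27061 were well above background on all 24 arrays. Pairs of arrays correlated with Pearson r of 0.966 to 0.997. The first principal component held 52.2% of the variance and separated the labelled diets, with scores of -39.6 to -19.6 for labelled control and 27.5 to 34.6 for labelled pesticide arrays. All values are log2 intensities of the median signal after quantile normalization.

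Sex-linked genes did not follow the sex labels. Xist, which female cells express from the X chromosome (probe A_52_P300376, mm9, chromosome X, 100662174 to 100662233), was well above background on 12 of 12 labelled pesticide arrays and on 0 of 12 labelled control arrays. Its mean was 5.08 ± 0.10 in labelled male control, 5.12 ± 0.24 in labelled female control, 8.24 ± 0.11 in labelled male pesticide and 8.21 ± 0.16 in labelled female pesticide livers (SD, n = 6 each). The Y-linked gene Eif2s3y (A_51_P479715, chromosome Y, 364900 to 364959) had the reverse pattern, at 10.94 ± 0.05, 10.99 ± 0.17, 5.08 ± 0.15 and 5.13 ± 0.16 in the same order. It was at least 45.9-fold lower in labelled pesticide than in labelled control males and at least 46.2-fold lower in females. Ddx3y (chromosome Y, 599275 to 599334) had means of 7.57 ± 0.10 and 7.42 ± 0.11 in labelled male and female controls and 5.01 ± 0.08 and 5.11 ± 0.12 in the labelled pesticide groups. Kdm5d and Uty, also on chromosome Y, were well above background on the 12 labelled control arrays only. Thus 12 arrays had sex-linked transcripts against their sex label, 6 labelled female control and 6 labelled male pesticide, and the other 12 matched it. The labelled diet therefore coincided with the sex-chromosome transcripts on every array, and no difference between labelled diets can be attributed to the pesticides. Groups are named by their labels throughout.

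**Figure D1:**
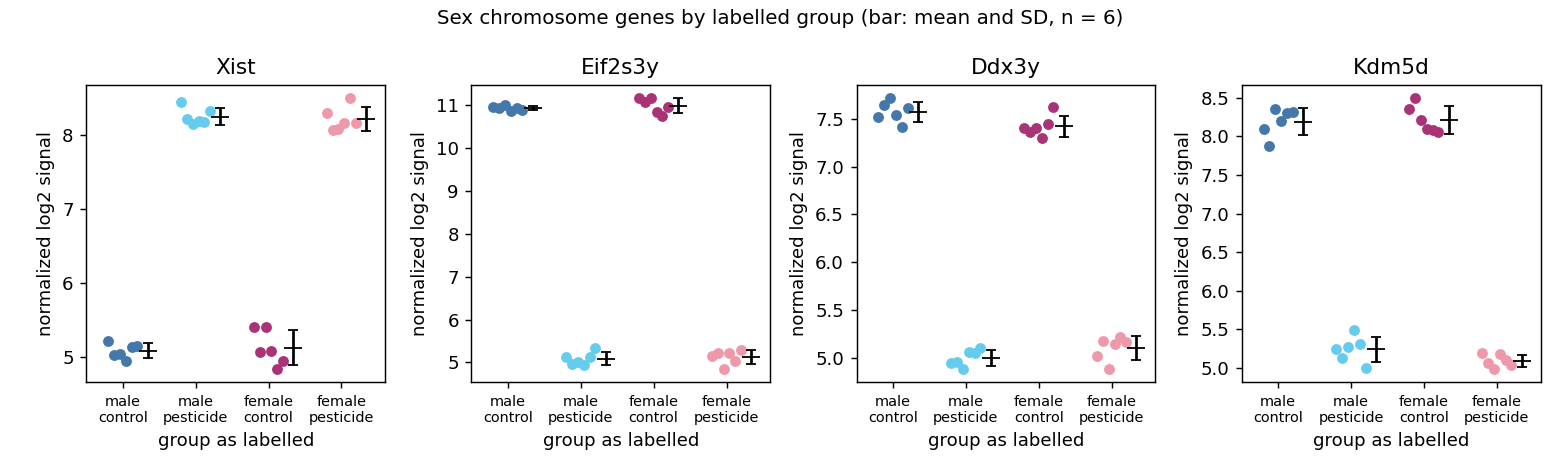
Log2 normalized intensity of Xist and Y-linked genes in each of the 24 arrays by labelled group (points, arrays; bars, mean and SD of 6 arrays). Xist lay at 8.07 to 8.49 on the labelled pesticide arrays and at 4.84 to 5.41 on the labelled control arrays, whichever sex was labelled.

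The comparison of labelled pesticide with labelled control males asked how the diet changed liver expression in males. The sulfotransferase gene Sult2a1 (A_55_P1952517, mm9, chromosome 7, 14381602 to 14381661) was at 16.70 ± 0.23 in labelled male pesticide and 5.08 ± 0.25 in labelled male control livers (SD, n = 6 each), a log2 fold change of 11.62 ± 0.17 (SE; limma adjusted p = 7.2e-25), at least 2451-fold higher. Cyp2b9 (chromosome 7, 26995607 to 26995666) rose from 7.26 ± 1.25 to 16.03 ± 0.23 and Cyp2b10 (chromosome 7, 26711522 to 26711581) from 8.02 ± 1.20 to 15.64 ± 0.26, by 8.78 ± 0.73 (adjusted p = 3.4e-09) and 7.63 ± 0.66 (adjusted p = 6.6e-09). Cyp4a12b (A_55_P2152607, chromosome 4, 115111580 to 115111639) fell by 9.21 (SE 0.16, adjusted p = 2.2e-23), from 14.64 ± 0.36 to 5.42 ± 0.14, where 1 of 6 arrays was well above background. Elovl3 (chromosome 19, 46209325 to 46209384) fell by 8.56 (SE 0.28, adjusted p = 1.4e-17). These changes coincide with the sex-linked genes.

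Among the 12 highest genes were also Sult2a2 (11.22 ± 0.10, at least 2006-fold), Sult2a6 (10.32, at least 1119-fold), Cyp3a44 (9.17 ± 0.29, at least 503-fold), Sult2a4 (9.02, at least 399-fold), Cyp2b13 (8.16 ± 0.55, at least 241-fold), Sult2a3 (7.20), A1bg (7.18 ± 0.48, at least 109-fold) and Sult3a1 (7.10, at least 112-fold). Sult2a3 was well above background on 2 of the 6 labelled male control arrays. The lowest were also Cyp4a12a (-8.23 ± 0.26), Hsd3b5 (-8.12 ± 0.42), Slco1a1 (-7.26 ± 0.20, at least 141-fold lower), Nat8f5 (-6.83), Nat8 (-6.04), Cidea (-5.94 ± 0.91), Eif2s3y (-5.85), Susd4 (-5.63), Tff3 (-5.21 ± 0.68) and Serpina4-ps1 (-5.14). In each of these genes the 6 arrays of one group lay wholly above the 6 of the other. Genes of the Sult2a, Cyp2b, Cyp3a and Cyp4a12 families are near-identical in sequence, so which member gave the signal is uncertain. Of the genes chosen in advance, Cyp3a11 rose by 2.49 ± 0.34 (adjusted p = 1.2e-05), Cyp2c29 by 1.14 ± 0.11 (5.7e-08) and Nqo1 by 0.71 ± 0.18 (0.0072), and Cidec (chromosome 6, 113374693 to 113374752) fell by 3.18 (SE 0.43, adjusted p = 1.1e-05). Cyp4a10 (0.40), Cyp4a14 (0.63), Fasn (0.30), Cyp7a1 (-0.16), Scd1 (-0.27) and Cyp1a2 (-0.36) did not pass, and Cyp1a1 was too dim to be tested. Cyp4a10 passed without labelled male control 5 (0.53, adjusted p = 0.039).

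In labelled males 7131 of 32078 probes (22.2%) passed, 3713 higher and 3418 lower, for 4030 genes, 2280 higher and 1750 lower. Of these, 811 probes and 539 genes changed more than 2-fold. With slide as a block 7540 probes passed, and within slides 1, 2 and 3, with 2 arrays per group, 1052, 583 and 459. Higher probes made up 52.1% of those that passed, 43.6% with the processed signal scaled to the 75th percentile and 38.1% with the median signal scaled so. Probes on the X and Y chromosomes made up 3.9% of those that passed.

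Of 48 female-biased liver genes written down in advance, 41 were higher, 3 lower and 4 did not pass in labelled males (42 and 3 adjusted over the list alone), with a median log2 fold change of 2.08. The median was 2.08 with the slide block and 1.72, 2.13 and 2.23 within the slides. Of 36 male-biased genes, 0 were higher, 28 lower and 8 did not pass (29 lower adjusted over the list alone), with a median of -1.85 (-1.85 with the slide block; -1.42, -2.22 and -1.79 within the slides). Both passed camera (adjusted p = 4.3e-41 and 9.5e-31) and held with an estimated correlation (8.9e-05 and 0.00034). So did the 5 sex chromosome genes, 1 higher and 4 lower and the same adjusted over the list alone (4.4e-08; 0.0028), and the 8 AhR target genes, 4 higher, 0 lower and 4 not passing, with 4 higher adjusted over the list alone (0.003; 0.022). The AhR median was 0.31 (0.31 with the slide block; 0.29, 0.32 and 0.36 within the slides), and its genes included Tiparp (0.51) and Fmo2 (2.21 ± 0.16), which was also in the female-biased list. The mean of the AhR members was 1.53 with an SD of 3.15, far above their median, and the call rested on few members. Leaving out each of the 8 in turn gave a camera adjusted p of 0.00045 to 0.079, with the call ended in 1 case, and 0.01 to 0.32 with an estimated correlation, with the call ended in 3.

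Several cell marker lists were higher in labelled male pesticide livers. Of 18 Kupffer cell and macrophage markers, 13 were higher, 0 lower and 5 did not pass (15 higher adjusted over the list alone), among them Vsig4 (1.88 ± 0.26, adjusted p = 1.1e-05), C1qa (1.53 ± 0.30) and Clec4f (1.43 ± 0.23). The list's camera adjusted p was 4.2e-07, and adjusted p = 0.42 with an estimated correlation. Its median of 1.22 was 1.22 with the slide block and 1.46, 1.44 and 0.92 within the slides. Of 16 endothelial markers, 9 were higher, 0 lower and 7 did not pass (13 higher adjusted over the list alone; 3.1e-05, adjusted p = 0.42 with an estimated correlation), including Cdh5 (0.62 ± 0.12) and Stab2 (0.52). Of 20 stellate cell and fibrosis markers, 14 were higher, 0 lower and 6 did not pass (15 higher adjusted over the list alone; 3.7e-05, adjusted p = 0.42 with an estimated correlation), including Bgn (0.56), Reln (0.50) and Dcn (0.44). Of 10 B and plasma cell markers, 6 were higher, 0 lower and 4 did not pass (8 higher adjusted over the list alone; 0.00031, adjusted p = 0.42 with an estimated correlation), including Cd79b (1.72 ± 0.35) and Ms4a1 (1.62). Of 18 T and NK cell markers, 6 were higher, 0 lower and 12 did not pass (9 higher adjusted over the list alone; 0.0035, adjusted p = 0.62 with an estimated correlation), including Gzma (1.64 ± 0.40). There were 12 T and NK cell markers higher without labelled female control 4, an array outside this comparison. Of 10 neutrophil markers, 3 were higher, 0 lower and 7 did not pass (3 higher adjusted over the list alone; 0.045, adjusted p = 0.6 with an estimated correlation), including S100a9 (1.42) and S100a8 (1.38). The neutrophil list's adjusted p was 0.061 without labelled female control 4. The median of the B and plasma cell markers was 2.4, 1.24 and 0.08 within slides 1, 2 and 3. Fry and an exact permutation test of list means do not compare a list with the other genes. Of the 17 lists camera called in labelled males, fry called 13, all but T and NK cell markers (adjusted p = 0.067), interferon response (0.15), cholesterol synthesis (0.2) and oxidative phosphorylation genes (0.13), and the permutation test 14, all but the last 3 of these. Kupffer cell markers had 0.0022 with fry and 0.0142 with the permutation test. Over all 36 lists fry called 17 and the permutation test 19.

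Of 37 interferon response genes, 11 were higher in labelled males, 0 lower and 26 did not pass (12 higher adjusted over the list alone; camera 0.00076, adjusted p = 0.74 with an estimated correlation), including Gbp3 (1.42) and Ifi27l2a (1.36). The list's median was 1.00, -0.03 and 0.60 within slides 1, 2 and 3, 0.58 with the slide block. Of 28 glucuronidation and sulfation enzymes, 10 were higher, 6 lower and 12 did not pass (12 and 7 adjusted over the list alone). Camera called the list higher (adjusted p = 3.1e-05, 0.12 with an estimated correlation), and the Sult2a genes are among its members. Its median was 0.15 with the slide block, far below its mean of 2.09. Of 32 CAR and PXR target genes, 12 were higher, 6 lower and 14 did not pass (12 and 7 adjusted over the list alone; called higher, 0.045, adjusted p = 0.6 with an estimated correlation). Their median was 0.07, or -0.02 with the median signal scaled to the 75th percentile, and the adjusted p was 0.061 without labelled female control 4 and 0.062 without labelled female pesticide 3. Of 24 cholesterol synthesis genes, 1 (Insig1, 0.63) was higher, 0 lower and 23 did not pass (0 adjusted over the list alone; called higher by camera, 0.024, adjusted p = 0.74 with an estimated correlation). Its median was -0.12, 0.36 and 0.67 within slides 1, 2 and 3.

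Of 26 bile acid genes, 2 were higher, 8 lower and 16 did not pass in labelled males (3 and 8 adjusted over the list alone; called lower, 0.03, adjusted p = 0.42 with an estimated correlation), including Cyp7b1 (-3.43 ± 0.25, adjusted p = 3e-10) and Nr1h4 (-0.42). Of 22 lipid droplet and steatosis genes, 2 were higher, 7 lower and 13 did not pass (3 and 8 adjusted over the list alone; called lower, 0.045, adjusted p = 0.6 with an estimated correlation), including Fitm1 (-2.54) and Mup20 (-1.86), while Vldlr rose (3.34 ± 0.33). Cyp7b1, Fitm1 and Mup20 were also in the male-biased list, and Vldlr in the female-biased list. The lipid droplet call was lost with the slide block (adjusted p = 0.054), with the median signal scaled to the 75th percentile (0.084) and without labelled female control 4 (0.054). Of 52 oxidative phosphorylation genes, 0 were higher, 7 lower and 45 did not pass (7 lower adjusted over the list alone; called lower, 0.024, adjusted p = 0.74 with an estimated correlation), including Ndufa4 (-0.30) and Uqcrc1 (-0.25). The lists that did not pass had camera adjusted p from 0.13 to 0.79. Among them, 5 of 38 PPARalpha target genes were higher and 1 lower, of 27 acute phase genes 5 and 2, and of 20 NRF2 target genes 4 and 0. Of 24 lipogenesis genes 2 were higher and 1 lower, of 18 clock genes 2 and 2, of 24 ER stress genes 0 and 2, and of 24 glucose and insulin response genes 1 and 4. Of 21 glutathione transferases 3 were higher and 5 lower, of 16 heat shock genes 3 and 2, of 22 cell cycle genes 1 and 1, and of 23 fetal liver and liver tumour genes 3 and 1. Among cell markers, of 12 hepatocyte genes 0 were higher and 1 lower, of 8 adipocyte genes 0 and 2, of 11 bile duct genes 2 and 0, and of 7 skeletal muscle genes 1 and 0. These counts were the same adjusted over the list alone. Of 8 erythroid markers 5 were higher and 1 lower (6 and 1 adjusted over the list alone), of 19 esterases and paraoxonases 7 and 5 (7 and 6), of 17 p53 target genes 5 and 1 (5 and 2), and of 6 exocrine pancreas markers 0 and 1 (0 and 2). Median and mean differed in sign for glutathione transferases (0.01 and -0.11) and heat shock genes (0.08 and -0.13).

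**Figure D2:**
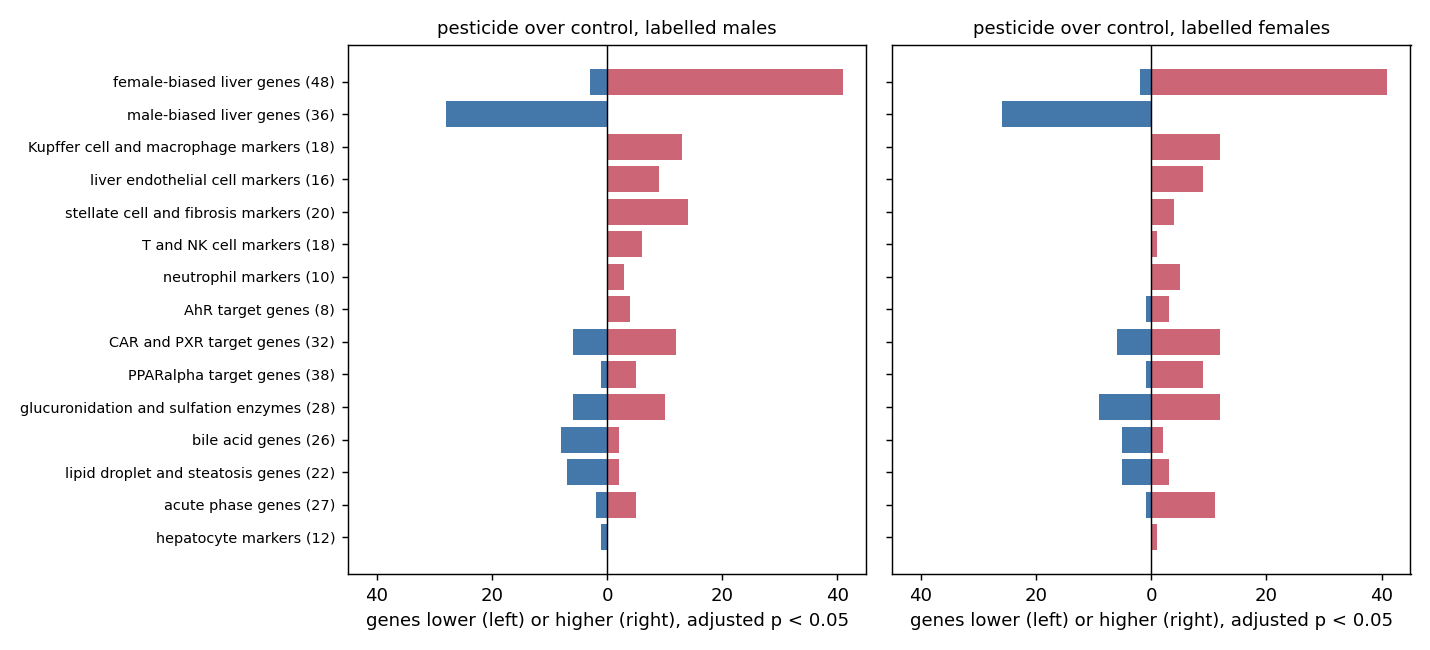
Number of members higher or lower (limma adjusted p under 0.05 over all probes) in a selection of the 36 gene lists, in labelled pesticide against labelled control males and females. Not all lists that camera called are shown. Among 48 female-biased genes 41 were higher in each labelled sex, and among 36 male-biased genes 28 and 26 were lower.

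The comparison of labelled pesticide with labelled control females asked the same in females, and the same genes led. Sult2a1 was at 16.45 ± 0.52 in labelled female pesticide and 5.11 ± 0.12 in labelled female control livers (SD, n = 6 each; log2 fold change 11.34 ± 0.17, limma adjusted p = 1.3e-24), at least 2140-fold higher. Cyp2b9 was at 15.89 ± 0.67 against 9.02 ± 2.34 (6.87 ± 0.73, adjusted p = 2.8e-07) and Cyp2b10 at 15.52 ± 0.60 against 9.32 ± 2.07 (6.20 ± 0.66, 2.8e-07). Cyp4a12b, at 5.43 ± 0.15 against 14.85 ± 0.42, was at least 658-fold lower (-9.43 ± 0.16, 1.3e-23). Cidea (chromosome 18, 67527351 to 67527410) was at 6.04 ± 0.29 against 13.43 ± 2.81 (-7.39 ± 0.91, 2.8e-06). As in labelled males, these changes coincide with the sex-linked genes.

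Among the highest genes in labelled females were also Sult2a2 (10.91 ± 0.10, at least 1799-fold), Sult2a6 (9.92, at least 957-fold), Sult2a4 (8.73, at least 333-fold), Cyp3a44 (8.48, at least 306-fold), Sult2a3 (7.52, at least 151-fold), Cyp2b13 (7.50 ± 0.55), A1bg (7.29, at least 117-fold) and Sult3a1 (6.59). Cyp2b13 was well above background on 2 and Sult3a1 on 1 of the 6 labelled female control arrays. The other lowest were Cyp4a12a (-8.68), Elovl3 (-7.03 ± 0.28), Nat8f5 (-6.93), Slco1a1 (-6.73, at least 91.0-fold lower), Hsd3b5 (-6.40), Eif2s3y (-5.86), Nat8 (-5.78), Serpina4-ps1 (-4.96), Susd4 (-4.78) and Cyp2d34 (-4.69). The 6 arrays of one group again lay wholly above those of the other in each. Cyp3a11 rose by 1.96 ± 0.34 (adjusted p = 0.00031), Cyp4a10 by 1.12 ± 0.19 (0.00017) and Cyp2c29 by 1.05 ± 0.11 (2.6e-07), and Cidec fell by 3.46 (SE 0.43, 3.9e-06). Cyp4a14 (0.73), Nqo1 (0.43), Cyp7a1 (0.23), Cyp1a2 (-0.22), Scd1 (-0.22) and Fasn (-0.51) did not pass.

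In labelled females 5878 probes (18.3%) passed, 2849 higher and 3029 lower, for 3315 genes, 1688 higher and 1627 lower; 612 probes and 424 genes changed more than 2-fold. Higher probes made up 48.5%, or 44.5% and 43.1% under the same scalings of the processed and the median signal. The slide block gave 6286 probes, and slides 1, 2 and 3 alone 1041, 319 and 346.

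In labelled females 41 of the 48 female-biased genes were higher, 2 lower and 5 did not pass (41 and 2 adjusted over the list alone), including Cux2 (4.58 ± 0.17, adjusted p = 1.5e-16). Their median was 1.76, the same with the slide block and 1.91, 1.75 and 1.76 within the slides. Of the 36 male-biased genes, 0 were higher, 26 lower and 10 did not pass (1 higher and 27 lower adjusted over the list alone), with a median of -1.74 (-1.74 with the slide block; -1.72, -1.82 and -1.41 within the slides). These lists (camera adjusted p = 1.6e-42 and 1.1e-28) and the 5 sex chromosome genes (1 higher, 4 lower, the same adjusted over the list alone; 1e-08) held with an estimated correlation (7e-05, 0.00053 and 0.0019). Of 18 Kupffer cell and macrophage markers, 12 were higher, 0 lower and 6 did not pass (12 higher adjusted over the list alone; 1.2e-05, adjusted p = 0.6 with an estimated correlation), including Vsig4 (1.65 ± 0.26, 8.4e-05). Their median of 1.05 (1.05 with the slide block) was 1.88, 0.45 and 0.86 within the slides. Of 16 endothelial markers, 9 were higher, 0 lower and 7 did not pass (13 higher adjusted over the list alone; 4e-06, adjusted p = 0.38 with an estimated correlation), including Stab2 (0.73). Of 10 neutrophil markers, 5 were higher, 0 lower and 5 did not pass (7 higher adjusted over the list alone; 0.0083, adjusted p = 0.6 with an estimated correlation), including S100a9 (1.62). Of 20 stellate cell and fibrosis markers, 4 were higher, 0 lower and 16 did not pass (5 higher adjusted over the list alone; 0.032, adjusted p = 0.83 with an estimated correlation), including Bgn (0.57). The stellate median was 0.46, -0.13 and 0.27 within slides 1, 2 and 3. Of the 13 lists camera called in labelled females, fry called 8 (12 of all 36) and the exact permutation test 8 (11 of all 36). Cell cycle, heat shock, PPARalpha target and stellate cell genes passed neither, acute phase genes passed the permutation test (0.00866) and not fry (0.052), and Kupffer cell markers fry (0.016) and not the permutation test (0.0866).

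Of 28 glucuronidation and sulfation enzymes, 12 were higher, 9 lower and 7 did not pass in labelled females (12 and 9 adjusted over the list alone). Camera called the list higher (adjusted p = 5e-05, 0.14 with an estimated correlation). Its median was 0.1 with the slide block, far below its mean of 2.03. Of 27 acute phase genes, 11 were higher, 1 lower and 15 did not pass (12 and 1 adjusted over the list alone; called higher, 0.00056, adjusted p = 0.81 with an estimated correlation), including Mt1 (2.85 ± 0.65) and Lbp (1.22). Of 38 PPARalpha target genes, 9 were higher, 1 lower and 28 did not pass (11 and 1 adjusted over the list alone; called higher, 0.014, adjusted p = 0.84 with an estimated correlation), including Acot3 (2.21) and Acsl1 (-0.60). Their median of 0.12 was 0.13, 0.27 and -0.02 within the slides, 0.12 with the slide block. Acot3 was also in the female-biased list. Of 8 AhR target genes, 3 were higher, 1 (Ugt1a6a, -0.34) lower and 4 did not pass (4 and 1 adjusted over the list alone; called higher, 0.016, adjusted p = 0.082 with an estimated correlation). Leaving out each AhR member in turn gave a camera adjusted p of 0.0022 to 0.29, with the call ended in 2 cases. The AhR median was 0.54, 0.22 and 0.01 within slides 1, 2 and 3. Of 22 cell cycle genes, 0 were higher, 7 lower and 15 did not pass (9 lower adjusted over the list alone; 0.00056, adjusted p = 0.83 with an estimated correlation), including Mcm5 (-1.69), Mcm6 (-1.46) and Ccne1 (-1.24). The cell cycle median was 0.01, -0.89 and -0.87 within slides 1, 2 and 3. Of 16 heat shock genes, 0 were higher, 4 lower and 12 did not pass (7 lower adjusted over the list alone; 0.0083, adjusted p = 0.83 with an estimated correlation), including Hspa1a (-1.93 ± 0.37). The lists that did not pass had camera adjusted p from 0.1 to 0.98. Of 32 CAR and PXR target genes 12 were higher and 6 lower (12 and 9 adjusted over the list alone), of 26 bile acid genes 2 and 5 (5 and 6), of 22 lipid droplet and steatosis genes 3 and 5 (3 and 6), of 24 glucose and insulin response genes 2 and 4 (4 and 4), of 21 glutathione transferases 2 and 5 (2 and 6), of 19 esterases and paraoxonases 6 and 5 (7 and 6), and of 17 p53 target genes 3 and 2 (4 and 4). Of 10 B and plasma cell markers and of 12 hepatocyte markers 1 was higher and 0 lower (0 adjusted over the list alone). Counts were the same adjusted over the list alone for 52 oxidative phosphorylation genes (0 higher, 4 lower), 24 ER stress genes (1 and 2), 20 NRF2 target genes (2 and 1), 24 lipogenesis genes (1 and 1), 18 clock genes (2 and 1), 23 fetal liver and liver tumour genes (3 and 3), 8 adipocyte markers (0 and 2) and 8 erythroid markers (0 and 1). For cholesterol synthesis genes, bile duct, exocrine pancreas and skeletal muscle markers 0 passed over all genes or adjusted over the list alone. Median and mean differed in sign for clock genes (0.02 and -0.04), fetal liver and liver tumour genes (0.13 and -0.04), NRF2 target genes (-0.11 and 0.01), hepatocyte markers (-0.01 and 0.01) and exocrine pancreas markers (-0.01 and 0.01). Also not passing, T and NK cell markers had 1 gene higher (1 adjusted over the list alone; adjusted p = 0.34) and interferon response genes 0 (0 adjusted over the list alone; 0.33). Without labelled female control 4 they had 11 (0.00025) and 12 (0.00034), and oxidative phosphorylation genes were called (0.047). B and plasma cell markers were called without labelled female pesticide 3 (0.049).

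The mean of the labelled male and female effects asked what was shared by both. Sult2a1 was higher by 11.48 ± 0.12, Sult2a2 by 11.06 ± 0.07 (limma adjusted p = 5.3e-33), Sult2a6 by 10.12, Sult2a4 by 8.87, Cyp3a44 by 8.83, Cyp2b13 by 7.83, Cyp2b9 by 7.82, Sult2a3 by 7.36, A1bg by 7.24, Cyp2b10 by 6.91 and Sult3a1 by 6.85. Sult2a1, Sult2a2, Sult2a4, Sult2a6, Cyp3a44 and A1bg were well above background on 0 of the 12 labelled control arrays, so their fitted differences and order depend on the background, and the bounds given for each labelled sex apply. The same holds for Slco1a1 and Eif2s3y, at background on the 12 labelled pesticide arrays. For Sult2a1 the fitted difference was 10.60 to 14.48 over the alternatives. Lower were Cyp4a12b (-9.32 ± 0.11), Cyp4a12a (-8.45), Elovl3 (-7.79), Hsd3b5 (-7.26), Slco1a1 (-6.99), Nat8f5 (-6.88), Cidea (-6.67), Nat8 (-5.91), Eif2s3y (-5.86), Susd4 (-5.21), Serpina4-ps1 (-5.05) and Cyp2d34 (-4.84). In all 11593 probes (36.1%) passed, 5613 higher and 5980 lower, for 6306 genes, 3261 higher and 3045 lower. Higher probes made up 48.4% of those that passed, 43.5% with the processed signal scaled to the 75th percentile and 39.4% with the median signal scaled so. The slide block gave 12059 and slides 1, 2 and 3 alone 3499, 1525 and 1792.

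Fry called 18 lists in the averaged effect, Kupffer cell markers among them (adjusted p = 0.00015). In the averaged effect 42 female-biased genes were higher, 3 lower and 3 did not pass (44 and 3 adjusted over the list alone; camera 2e-36, 2e-04 with an estimated correlation), and 28 of 36 male-biased genes were lower, 0 higher and 8 did not pass (28 lower adjusted over the list alone; 1.6e-25, 0.0011). The sex chromosome genes also held (1.7e-06, 0.0096). Among cell markers, 14 of 18 Kupffer (15 adjusted over the list alone), 14 of 16 endothelial (14), 13 of 20 stellate (14), 6 of 10 B and plasma cell (7), 7 of 10 neutrophil (7) and 8 of 18 T and NK cell markers (8) were higher, with 1 T and NK cell marker lower, adjusted over the list alone too. Their camera adjusted p were 1.2e-06, 3.1e-06, 0.00074, 0.0046, 0.013 and 0.028, against an adjusted p = 0.57, 0.38, 0.6, 0.6, 0.6 and 0.76 with an estimated correlation. Of 27 acute phase genes 14 were higher and 2 lower (15 and 2 adjusted over the list alone; 0.0094), of 37 interferon response genes 12 higher and 0 lower (12 adjusted over the list alone; 0.015), of 22 cell cycle genes 1 higher and 9 lower (1 and 9 adjusted over the list alone; 0.026), and of 52 oxidative phosphorylation genes 0 higher and 8 lower (6 adjusted over the list alone; 0.046), each with adjusted p = 0.76 with an estimated correlation. The interferon median was 0.90, -0.15 and 0.16 within slides 1, 2 and 3, and 0.35 with the slide block. Of 8 AhR target genes 4 were higher and 0 lower (4 and 1 adjusted over the list alone; 0.015, adjusted p = 0.077 with an estimated correlation; 0.0038 to 0.18 leaving out each member), and of 28 glucuronidation and sulfation enzymes 13 were higher and 8 lower (13 and 10 adjusted over the list alone; 0.00089, adjusted p = 0.32 with an estimated correlation). The median of the glucuronidation and sulfation enzymes was 0.11 with the slide block. Without labelled female control 4 the cell cycle genes no longer passed (0.095) and 13 T and NK cell markers were higher. Without labelled female pesticide 3 the oxidative phosphorylation genes did not pass (0.051). With the median signal scaled to the 75th percentile the acute phase genes (0.07) and the cell cycle genes (0.058) did not pass.

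The interaction asked whether the labelled male and female effects differed. Eva1c (-1.07 ± 0.23), Fbxo31 (-1.04 ± 0.23), Igsf9 (-0.98 ± 0.24) and Ldlrad3 (-0.88 ± 0.22) had the smallest p among genes lower in it, and Mob3a (0.67 ± 0.17), Mcidas (0.64 ± 0.16) and Umps (0.49 ± 0.13) among those higher, each with limma adjusted p = 0.52. With limma, 0 probes passed and 1265 had an unadjusted p under 0.05, against 1604 given by chance; the slide block gave 0 too. Of 15949 genes, 1261 were higher in both labelled sexes and 1077 lower in both, against 241 and 179 for independent lists, and 1 was opposite. The log2 fold changes of the labelled sexes correlated across genes with Pearson r 0.916 (jackknife SE over arrays 0.029) and Spearman rho 0.766, where genes are not independent replicates. Of 100 regroupings of the diet labels, the real one included, 1 gave r as large, and the others gave -0.78 to 0.77. In both labelled sexes the real grouping parted arrays with Y-linked transcripts from arrays with Xist, so this says nothing on the pesticides. Within slides 1, 2 and 3 r was 0.863, 0.737 and 0.809, and with the slide block 0.916. Across genes, the labelled sex differences under the control and the pesticide label correlated with r 0.07. Camera called 17 lists (11 higher, 6 lower) in the interaction, 0 of them with an estimated correlation, and fry called 0. The medians of several, among them B and plasma cell markers and cell cycle genes, turned sign within a slide. Adjusted over the list alone, 2 male-biased genes and 1 hepatocyte marker were lower and no other member of these lists passed. AhR target genes, bile acid genes and exocrine pancreas markers had an adjusted p = 0.31 with an estimated correlation. B and plasma cell markers, hepatocyte markers, female-biased, male-biased, heat shock and NRF2 target genes had 0.5, cell cycle, cholesterol synthesis and stellate cell genes 0.53, acute phase genes and T and NK cell markers 0.63, interferon response and PPARalpha target genes 0.66, and lipogenesis genes 0.68. Without labelled female control 4 the calls of AhR target genes (adjusted p = 0.08), stellate cell markers (0.084), T and NK cell markers (0.33) and interferon response genes (0.45) ended. Without labelled female pesticide 3, Kupffer cell and macrophage markers were called (0.049).

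**Figure D3:**
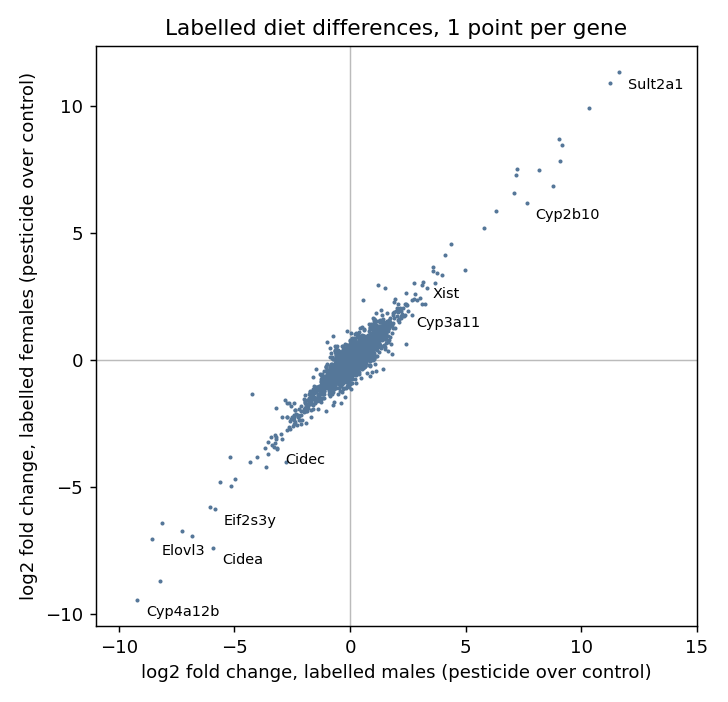
Log2 fold change of labelled pesticide against labelled control, in labelled females (y) against labelled males (x), for each of 15949 genes. The points follow 1 diagonal (Pearson r 0.916), with the Sult2a genes at the upper end and Cyp4a12b at the lower end.

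Labelled males and females of the control diet were compared to ask how the sexes differed without pesticides. All 12 of these arrays carried Y-linked transcripts and no Xist well above background. Thus no sex difference could be measured between the labelled males and females. Xist (-0.04 ± 0.09, limma adjusted p = 1) and Ddx3y (0.15 ± 0.07, adjusted p = 0.85) did not differ detectably between them, at the means given above. With limma, 0 probes passed and 1792 had an unadjusted p under 0.05, against 1604 given by chance, and the smallest adjusted p was 0.19; the slide block gave 0. Of 20 NRF2 target genes, 20 had a negative difference, 0 passed over all genes and 5 were lower adjusted over the list alone, including Srxn1 (-0.52 ± 0.11), Gclc (-0.41), Gsta2 (-0.89) and Nqo1 (-0.52 ± 0.18). The NRF2 list was called by camera (median -0.37, adjusted p = 4.9e-09), with adjusted p = 0.19 with an estimated correlation, and its median was 0.02, -0.57 and -0.52 within slides 1, 2 and 3, -0.37 with the slide block. Lipid droplet and steatosis genes were lower (median -0.21, 0.00028, adjusted p = 0.28 with an estimated correlation; 5 lower adjusted over the list alone), including Cd36 (-1.14 ± 0.29) and Cidec (-1.62 ± 0.43), as were PPARalpha target genes (median -0.15, 8.2e-09, adjusted p = 0.28 with an estimated correlation; 1 lower adjusted over the list alone), including Fgf21 (-0.97 ± 0.23). Within slides 1, 2 and 3 these medians were -0.08, -0.55 and -0.16 for lipid droplet and -0.14, -0.23 and -0.15 for PPARalpha target genes. Camera called 21 lists (6 higher, 15 lower), 0 of them with an estimated correlation, and fry called 0. Adjusted over the list alone, 4 male-biased genes were higher and 4 female-biased genes lower. In the exocrine pancreas, hepatocyte and acute phase lists 1 gene each was higher, and 1 each lower in the p53 target, stellate cell and cell cycle lists. Glucose and insulin response genes had an adjusted p = 0.19 with an estimated correlation, and bile acid, female-biased, male-biased and p53 target genes and exocrine pancreas, hepatocyte and stellate cell markers 0.28. CAR and PXR target genes had 0.37, glutathione transferases 0.4, cell cycle genes and erythroid markers 0.47, cholesterol synthesis genes 0.54, acute phase and heat shock genes and T and NK cell markers 0.58, lipogenesis genes 0.63 and interferon response genes 0.69. Without labelled female control 4 the calls of cell cycle (adjusted p = 0.055), p53 target (0.058), interferon response (0.14) and heat shock genes (0.23) and of exocrine pancreas (0.07) and T and NK cell markers (0.4) ended. Oxidative phosphorylation genes were called without it (0.01). With the median signal scaled to the 75th percentile, glutathione transferases were not called (0.064). Within slide 1 the median had the opposite sign for cell cycle genes (0.49), T and NK cell markers (0.22), lipogenesis (0.15), cholesterol synthesis (0.09), interferon response (0.07), glutathione transferase (0.03), female-biased (0.01) and CAR and PXR target genes (0.01), all called lower. So it had for exocrine pancreas markers (-0.09), acute phase (-0.08) and male-biased genes (-0.05), called higher, and within slide 3 for stellate cell markers (0.02). For p53 target and bile acid genes it was 0 within slide 1.

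Labelled males and females of the pesticide diet were compared for the sex difference under pesticides. All 12 of these arrays carried Xist and no Y-linked transcript well above background, so no sex difference could be measured between them. The 38 PPARalpha target genes, a list of genes switched on by the fatty acid receptor PPARalpha, all had a negative difference, with a median of -0.27. The list mean was 13.92 ± 0.20 in labelled male and 14.29 ± 0.18 in labelled female pesticide livers (SD, n = 6 each), against 13.72 ± 0.22 and 13.99 ± 0.18 in the labelled control groups. Pex11a (-0.79 ± 0.18), Cyp4a10 (-0.80 ± 0.19) and Ehhadh (-0.79 ± 0.19) were lower, each with limma adjusted p = 0.72, and over all genes 0 members passed against 19 lower adjusted over the list alone. Camera called the list (adjusted p = 9.3e-30), also with an estimated correlation (0.043), but not fry (0.1) or an exact permutation test of the list mean (p = 0.013, adjusted over the 36 lists 0.208). Its median was -0.27 with the slide block and -0.22, -0.35 and -0.29 within the slides.

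Of 22 lipid droplet and steatosis genes, 19 had a negative difference between labelled male and labelled female pesticide livers, with a median of -0.35, 0 passing over all genes and 7 lower adjusted over the list alone. They included Plin4 (-1.28), Cidec (-1.33 ± 0.43) and Plin5 (-0.53). The list mean was 11.66 ± 0.13 against 12.09 ± 0.16 (SD, n = 6 each). Camera called the list (4.6e-11; 0.043 with an estimated correlation), and an exact permutation test gave p = 0.00433, adjusted over the lists 0.156. Within the slides its median was -0.46, -0.45 and -0.30, with the slide block -0.35. Leaving out each array ended the estimated-correlation call of the PPARalpha list in 16 of 24 cases (adjusted p 0.016 to 0.14) and of the lipid droplet list in 17 (0.037 to 0.14). B and plasma cell markers were higher by camera (median 0.74, 1.2e-09, adjusted p = 0.16 with an estimated correlation; 5 higher adjusted over the list alone), including Ms4a1 (1.04) and Mzb1 (0.91), with medians of 1.45, 0.69 and 0.09 within slides 1, 2 and 3. In all, camera called 9 lists (4 higher, 5 lower) and fry 0. Heat shock genes (6.3e-05), interferon response genes (0.016) and cholesterol synthesis genes (0.026) were called higher, and oxidative phosphorylation genes (2e-04), neutrophil markers (0.039) and NRF2 target genes (0.048) lower, with 0 members passing adjusted over the list alone. Heat shock, oxidative phosphorylation, neutrophil and NRF2 lists had an adjusted p = 0.85 with an estimated correlation, and interferon response and cholesterol synthesis genes 0.91. Within slides 1, 2 and 3 the median was -0.24, 0.51 and 0.18 for cholesterol synthesis genes, -0.91, -0.16 and 0.07 for neutrophil markers, -0.22, -0.04 and 0.00 for NRF2 target genes and 0.46, 0.00 and 0.11 for heat shock genes. The NRF2 call was lost with the slide block (0.062) and with the median signal scaled to the 75th percentile (0.14). T and NK cell markers (0.016) and p53 target genes (0.043) were called without labelled female control 4, an array outside this comparison. Without labelled female pesticide 3, endothelial markers (0.013) and p53 target genes (0.042) were called. With limma, 0 probes passed in this comparison and 1311 had an unadjusted p under 0.05, against 1604 given by chance; the smallest adjusted p was 0.72, and the slide block gave 0.

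**Figure D4:**
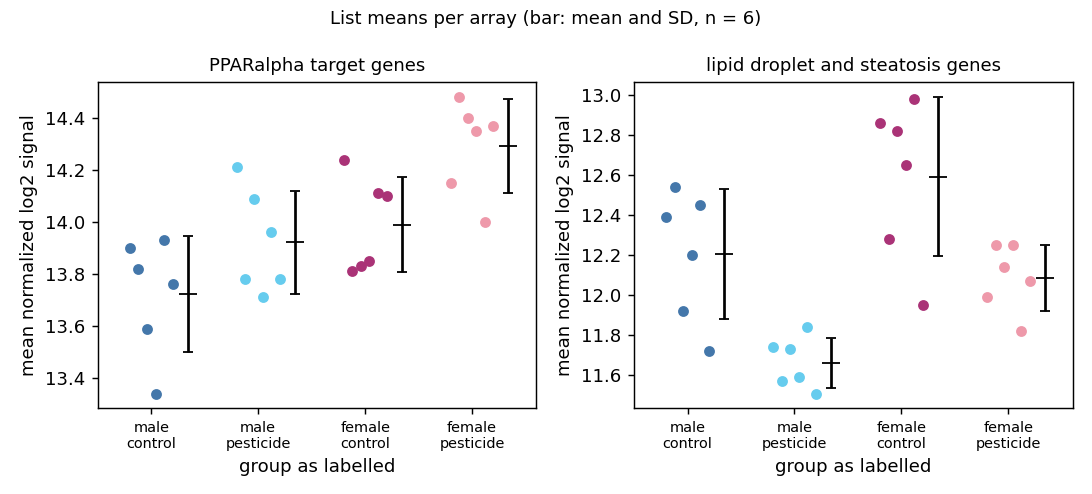
Mean log2 intensity of the PPARalpha target genes and of the lipid droplet and steatosis genes in each array by labelled group (points, arrays; bars, mean and SD of 6 arrays). In each labelled diet both lists were lower in labelled males, at 13.92 against 14.29 and 11.66 against 12.09 for the labelled pesticide groups.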

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

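Chosen only after the result was seen were the tests of wrong sex names, of the diet acting on sex-linked genes, of mixed RNA and of exchanged scanner files, those of the share of hepatocytes and of chance for the PPARalpha list, those of array quality and immune cells, and the splits of the interaction and of the labelled sex comparisons.

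Xist was present on the 12 labelled pesticide arrays and Y-linked genes on the 12 labelled control arrays, so the sex-linked genes followed the diet label. If the diet had acted on these genes in mice of the labelled sexes, labelled females of the control diet would carry no Y-linked transcripts, but over 4 Y-linked genes the median of labelled female control was 2.69 log2 units above labelled male pesticide livers. RNA mixed from both sexes is argued against by the 0 arrays with Xist and Eif2s3y both well above background. Wrong sex names of the labelled female control and labelled male pesticide groups, or an exchange of these group names, may explain it and cannot be told apart, since either gives 12 of 12 of these arrays the levels of the other sex. Exchanged single scanner files stay open as well, since 24 of 24 files match their own column of the value table, which would carry the same exchange.

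PPARalpha target genes were lower in labelled male than in labelled female livers of the labelled pesticide diet. The difference was at least as low as -0.22 within each slide and -0.28 under either 75th percentile scaling, which argues against slide and normalization as its whole cause. The hepatocyte markers differed by a median of -0.01, with an SE of 0.05 over 12 marker genes and not over livers. Their list mean was 17.05 ± 0.08 in labelled male and 17.08 ± 0.07 in labelled female pesticide livers (SD, n = 6 each). This argues against a lower share of hepatocytes as the whole cause. Less fasting before death may contribute and cannot be told apart, as a score of 7 genes raised and 5 lowered by fasting differed by -0.46 (exact permutation p = 0.303); neither can chance, as the exact permutation p of 0.013 is 0.208 adjusted over 36 lists. A difference between the sexes is argued against by the sex-linked genes. On all 12 arrays compared, Xist was well above background and none of the 4 Y-linked genes was. A difference between the diets stays open, since the labels conflict with the sex-linked genes.

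Labelled female control 4 stood furthest apart in T and NK cell markers. Of 3 quality measures, 0 lay outside the range of the other 23 arrays, which argues against array quality. Blood left in the liver piece is argued against by the erythroid list mean, at -1.09 SD from the highest other labelled control array. Its T and NK cell list mean was 9.50 against 7.54 ± 0.27 (SD) in the 11 other labelled control arrays, 5.24 SD above the highest of them (8.06), and a higher share of immune cells stays open, since this is the pattern itself and B and plasma cell and neutrophil markers lay at -0.69 and -0.82 SD from the highest other array. Lists of other kinds also lay above every other labelled control array. Fetal liver and liver tumour genes did so by 1.93 SD, stellate cell and fibrosis markers by 1.80 and p53 target genes by 1.27. Bile duct cell markers (0.45), heat shock (0.28), AhR target (0.23), cell cycle (0.05) and NRF2 target genes (0.01) did so by less. Kupffer cell and macrophage markers lay above by 1.91 and interferon response genes by 0.83. The lists of other kinds were not weighed, and the design names no difference that sets this sample apart.

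Values far from the other 5 arrays of their group were looked for in 268 groups (152 of named genes, 116 of gene lists), and 25 were found (15 and 10), by the gap to the nearest array as a share of the group's range, above the critical value of Dixon's test for 6 arrays. Chance gives about 1 in 20 groups, here 13. Labelled female pesticide 3, the array with the highest median signal, was low in Cyp2b10 (0.82), Cyp2b13 (0.79), Cyp2b9 (0.92) and the sex chromosome genes (0.69). This array also had the most probes well above background (39032, next 33393) and the lowest slope of the spike-in control signals (0.94, next 0.986). Whether this gave the low values was not tested. Labelled female pesticide 2 was high in Cyp4a12a (0.74), Hsd3b5 (0.72), Mcidas (0.63) and the NRF2 target genes (0.69) and low in Igsf9 (0.83), Ldlrad3 (0.86) and the hepatocyte markers (0.77). Among labelled male pesticide arrays, Cyp4a12a was high in array 4 (0.80), Mob3a low in array 1 (0.68), erythroid markers (0.89) and interferon response genes (0.69) high in array 2, and heat shock genes low in array 4 (0.72). Among labelled male control arrays, Cyp4a14 was low (0.75) and heat shock genes high (0.88) in array 4 and Fasn low (0.63) and Ldlrad3 high (0.78) in array 6. Among labelled female control arrays, Elovl3 was low in array 6 (0.68), Nqo1 low (0.72) and exocrine pancreas markers high (0.66) in array 2, and Kupffer cell and macrophage markers (0.80) and T and NK cell markers (0.63) high in array 4.

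The labelled male and female effects differed by camera's test of the interaction in 17 lists. Their median interaction was 0.62 for B and plasma cell markers, 0.50 for T and NK cell markers, 0.47 for cell cycle, 0.40 for cholesterol synthesis, 0.35 for interferon response, 0.31 for heat shock, 0.26 for AhR target, 0.26 for lipogenesis, 0.24 for stellate cell and fibrosis, 0.22 for NRF2 target and 0.14 for female-biased genes. It was -0.15 for acute phase genes, -0.14 for exocrine pancreas markers, -0.12 for PPARalpha target, -0.09 for bile acid, -0.07 for male-biased genes and -0.03 for hepatocyte markers. None held with an estimated correlation (lowest adjusted p 0.31), fry called 0 and limma 0 probes, with 1265 at an unadjusted p under 0.05. Within slides 1, 2 and 3 the median turned sign for B and plasma cell markers (1.59, 0.92 and -0.37), T and NK cell markers (0.25, 0.98, -0.03), cell cycle (-0.34, 1.24, 0.59), cholesterol synthesis (-0.30, 0.74, 0.79), lipogenesis (-0.34, 0.54, 0.75), NRF2 target (-0.16, 0.47, 0.46), stellate cell (-0.07, 0.73, 0.07), AhR target (-0.06, 0.41, 0.31) and male-biased genes (0.12, -0.42, -0.28). Without labelled female control 4 the calls of interferon response genes (adjusted p 0.45), T and NK cell markers (0.33), stellate markers (0.084) and AhR target genes (0.08) ended.

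Regrouped arrays did not reach the counts of the labelled pesticide comparisons. The real split also parted arrays with Y-linked transcripts from arrays with Xist. Its high counts could thus be foreseen from the sex-linked genes and say nothing on the pesticides. With the real split counted, 1 of 100 is also the least the test can give. Of 100 splits of the arrays, the real one included, 1 gave as many probes in labelled males (7131, highest other 1628), 1 in labelled females (5878, highest other 2330) and 1 in the averaged effect (11593, highest other 7929). The splits say nothing on the interaction (0 probes, highest other 1) or on labelled sex under the control label (0, highest other 15) and under the pesticide label (0, highest other 3), since with 0 real probes each of the 100 splits gives as many. The real limma counts of 0 stood beside 1265, 1792 and 1311 probes at an unadjusted p under 0.05.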

How the results depend on the processing

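Chosen only after the data were seen were the counts without X and Y probes and without labelled female control 4 or female pesticide 3, the labelled sex contrast averaged over the diets, the permutation tests of lists and the AhR target genes without each member.

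The counts of probes in the labelled pesticide comparisons stayed within 1.5 times the reported ones, except where fewer probes or arrays were used. The step meant to leave out X and Y probes gave 7131, 5878 and 11593, the reported counts. Of the passing probes 3.9%, 3.8% and 3.6% lay on these chromosomes, so this step cannot have removed them and tested nothing. With 1 probe per gene, which tests fewer probes, they were 4217 in labelled males, 3506 in labelled females and 6440 averaged. Slides 1, 2 and 3 alone, with 2 arrays per group, gave 1052, 583 and 459, then 1041, 319 and 346, then 3499, 1525 and 1792. The other alternatives reached 9147, 6751 and 12774, and leaving out 1 array gave 5921 to 7483, 4777 to 6526 and 10793 to 12024. The interaction stayed at 0 under each alternative run, and leaving out 1 array gave 0 to 0. Labelled sex under the control label gave 0 to 1 when 1 array was left out: Eva1c without female control 1 (adjusted p = 0.047) and Rlf without female control 6 (0.023). Under the pesticide label it gave 0 to 1, Rgs1 without female control 4 (limma adjusted p = 0.0077, against 0.72 with it). That array is outside this comparison. The Rgs1 difference was -0.87 with and without it, so the call came from the spread shared by all groups. Slide 1 alone gave 2 probes with no gene name (adjusted p = 0.031, log2 1.84 and 1.66). These genes and probes were chosen after their values were seen. For Eva1c, Rlf and the slide 1 probes the cause was not tested.

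The correlation of the labelled male and female effects was 0.88 with no filter on dim probes, 0.879 with probes well above background on all arrays, 0.879 without sex-biased genes, and 0.863, 0.737 and 0.809 within slides 1, 2 and 3; the cause was not tested for the filters. Leaving out 1 array gave 0.898 to 0.924.

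The 85 named gene results that passed and were checked kept their direction and side of the threshold in all 3060 alternatives run. This check, and the next on results that did not pass, left out genes named only as list members. Each slide alone was left out of both as well. Of 47 named results that did not pass, 1 passed under an alternative, Cyp4a10 in labelled males without male control 5 (0.53, adjusted p = 0.039). In 10 of them the sign changed under some alternative, as for Fasn in labelled males (-0.07 to 0.47) and Cyp7a1 in labelled sex under the control label (-0.11 to 0.20). Of the list calls, 92 in all, 311 alternatives kept the call and 149 did not: 80 with an estimated correlation, 60 with fry, 5 with the median signal scaled to the 75th percentile, 2 with the slide block and 2 with the replicate block, and 0 reversed. The replicate block ended the calls of lipid droplet genes in labelled males (adjusted p = 0.058) and of NRF2 target genes in labelled sex under the pesticide label (0.065). Preset-correlation list calls were recomputed without an array only for female control 4 and female pesticide 3.

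The labels do not say that arrays of the same number belong together, and the residuals of same-numbered arrays correlated at -0.17 to 0.37, with 14 of 36 above 0.1, so the arrays were not treated as paired. The mean of these correlations was 0.10, against -0.02 for arrays of other numbers and 0.03 for arrays of 1 slide, and 15 of 24 arrays correlated best with an array of their own number, a hint from the data that the numbers share something. A replicate block gave 8099, 6751 and 12652 probes in the labelled pesticide comparisons. Signal limits folds of genes at background, given as bounds: 29935 to 39032 of 56605 probes were well above background per array.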

Other observations

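The tests of exchanged group names, their repeat without labelled female control 4 and the labelled sex contrast averaged over the diets were chosen only after the result was seen.

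Labelled female control 4 differed from the 11 other labelled control arrays in several immune genes, picked after their values were seen. It was higher in Tgtp2 by 4.78, Ccl5 by 4.71, Ccl8 by 4.45, Ubd by 4.41, Nkg7 by 3.82, Cd74 by 3.64 and Cxcl9 by 3.49 log2 units. Cd74 was at 15.58 there. Other genes, picked in the same way, were lower there, among them Cish (-2.64), Onecut1 (-2.48) and Lpin1 (-1.85). The list means of glucose and insulin response genes (13.23, lowest other 13.28) and of sex chromosome genes (7.70, 7.73) also lay below the other labelled control arrays. Its Kupffer cell and macrophage list mean was 11.24 and its interferon response list mean 11.50, against a highest of 10.58 and 11.07 in the other labelled control arrays. Fetal liver and liver tumour genes (9.61, highest other 9.27), stellate cell and fibrosis markers (9.85, 9.44) and p53 target genes (10.76, 10.55) were also higher there. Bile duct cell markers and heat shock, AhR target, cell cycle and NRF2 target genes lay above the highest other array by 0.45 SD at most. B and plasma cell markers (7.39, highest other 7.66) and hepatocyte markers (17.11) did not stand apart.

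If the group names of the labelled female control and labelled male pesticide livers had been exchanged, the sex-linked genes would follow the sex, and each labelled sex would hold 1 of the 2 diets. A diet difference alike in both sexes would then appear as a labelled sex difference in the same direction under both diet labels. A diet difference unlike in the 2 sexes need not, and the tests below could miss it. The mean of the labelled sex differences of the PPARalpha target genes was -0.32, with a permutation p of 0.00067 over 100000 resamples (adjusted over the 36 lists 0.024). That list had already been seen to be lower under the pesticide label, and under the control label alone its exact permutation p was 0.0519. Across all genes the labelled sex differences under the 2 diet labels correlated with r 0.07 (permutation p = 0.636 over 1000 regroupings, the others -0.42 to 0.36), which gives no sign of a shared difference. An exchange of names therefore may or may not have happened, and these tests leave it open. Lipid droplet and steatosis genes (0.0017, adjusted 0.031), p53 target genes (0.0043, 0.049) and NRF2 target genes (0.0055, 0.049) also moved one way over both labels. By exact permutation under the control label alone p was 0.0931, 0.0779 and 0.026 for these lists, and under the pesticide label alone 0.00433, 0.0173 and 0.0866, and none of these passed when adjusted over the lists. Leaving out labelled female control 4, the adjusted p over both labels was 0.032 for PPARalpha target, 0.069 for lipid droplet, and 0.11 for p53 and for NRF2 target genes, so only the first still passed. With the averaged contrast limma called 0 probes, with 1794 at an unadjusted p under 0.05. Camera called 12 lists (2 higher, 10 lower), and with an estimated correlation PPARalpha target and lipid droplet genes (adjusted p = 0.038 each). Fry called 3, these (0.016 each) and NRF2 target genes (0.049), against 0 under either diet label alone. Wrong sex names remain open too, since the labels alone do not tell which name was changed, and the result attributes nothing to the pesticides.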
